A study of Mus musculus with 12 samples.

How the data were processed

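RNA of 12 samples was measured, 4 from each of the proliferative, prehypertrophic and hypertrophic zones of the femoral growth plate of 14-day-old mice. The zones had been microdissected from cryosections, and the RNA was amplified before labelling with Cy3 or Cy5. Each of the 6 two-colour arrays held samples of 2 zones, and each pair of zones was on 2 arrays of opposite dye. Array 1 paired hypertrophic replicate 1 (Cy3) with proliferative replicate 1, array 2 proliferative replicate 2 (Cy3) with hypertrophic replicate 2, and array 3 hypertrophic replicate 3 (Cy3) with prehypertrophic replicate 1. Array 4 paired prehypertrophic replicate 2 (Cy3) with hypertrophic replicate 4, array 5 prehypertrophic replicate 3 (Cy3) with proliferative replicate 3, and array 6 proliferative replicate 4 (Cy3) with prehypertrophic replicate 4.

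Per the file headers, the deposited scanner files hold the processed signal of 1 channel as an intensity, made with Agilent Feature Extraction 8.1.1.1. That software had subtracted the background, removed spatial trends and normalized the 2 dyes within each array, and no normalization between arrays was found. The deposited files also hold other values, flags of 0 or 1 per spot for saturation, for non-uniform or outlying spots and for being well above background (multiplier 2.6). A further deposited table gives log2 values per probe, which equal the log2 processed signal less the array's 75th percentile. Of its 12 columns, 1 matched its own sample's scanner file best, 6 matched a file of the same zone, and all 12 matched the file that has the same rank when the samples are sorted by title (41232 probes compared). The names of the table or those of the scanner files must therefore be wrong. With the names of the scanner files, the dye on the label equals the channel of the file in all 12 samples, all 6 arrays hold 2 zones, and samples of 1 zone correlate at 0.958 to 0.977. With the names of the table, these are 6 samples, 5 arrays and 0.902 to 0.977, and 0 features are called in any comparison, with outlier-flagged spots kept. The table was not used here, and all values come from the scanner files.

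The 2 channels of an array were joined by spot, and the log2 ratio of processed signals was normalized within each array by limma's loess, with control spots and spots with an outlier flag at weight 0. Ratios with an outlier flag in either channel were left out of the fit (3839, of which 2458 were on array 2), and spots of 1 probe were averaged. Of 43790 spots, 41534 were no controls, and they held 41174 probes, 40 of them spotted 10 times. Probes well above background in at least 4 of the 12 samples were kept (40016 kept, 1158 removed). Gene names came from the array's own annotation, which named 1 symbol for 32691 probes and none for 8483. Of the named probes, 32505 had a gene number in the RefSeq table used, and 0 symbols changed. Where a gene had several kept probes (8439 genes) the one with the highest mean brightness was used. This left 27240 features, 19351 with a symbol and 7889 without, and 27173 had enough ratios for a test. Levels per sample are the log2 channel value after loess less the sample's 75th percentile.

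A linear model with zone and a dye term was fitted to the 6 ratios of each feature with limma 3.58.1 in R 4.3.3, with moderated variances (eBayes, 3 residual and 1.22 prior degrees of freedom). The 3 differences between zones were tested with a Benjamini-Hochberg adjusted p of 0.05 over all features, separately for each. A feature counted as highest or lowest in the prehypertrophic zone when both steps along the axis passed in opposite directions. Where the lower zone was not well above background in any sample, the change is given as a lower bound. Saturated spots compress a ratio, and the report says where this applies. The median residual SD of a log2 ratio was 0.0910, and the SD among spots of 1 probe on 1 array was 0.0647. The median change of all features was -0.03, 0.02 and -0.04 in the 3 comparisons. As a check, the hypertrophic to proliferative ratio measured directly was compared with the one through the prehypertrophic zone. They correlated at 0.900 across features, which are not independent replicates, with a median absolute difference of 0.0901 against a median absolute ratio of 0.308.

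The pipeline was tested on simulated data, with known changes added to features in the measured noise. In hypertrophic against proliferative it recovered 58.8% of 51 changes of 2-fold and 75.5% of 49 changes of 4-fold with 5 false calls. In prehypertrophic against proliferative it recovered 59.2% of 49 and 76.5% of 51 with 8 false calls. These were the only features changed in each comparison, out of 27240, whereas 45.9% to 58.9% of the tested features were called in the data. The recovery and the false calls may therefore differ in the data.

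Gene lists, the tests of genes and lists, the rule for named genes and the alternatives, except keeping spots with an outlier flag, were fixed before the data were examined. Some tests of possible explanations, named below, were chosen afterwards. The 24 lists hold 449 genes, of which 431 were measured. They cover chondrocyte matrix, resting or superficial chondrocyte, hedgehog and PTHrP signalling, hypertrophic chondrocyte, mineralisation and phosphate handling, cell cycle, cell cycle inhibitors, matrix-degrading proteases and inhibitors, glycolysis and hypoxia, oxidative phosphorylation, unfolded protein response and secretion, BMP and TGF-beta signalling, Wnt signalling, FGF, IGF and growth hormone signalling, cell surface antigens, lysosome and autophagy, and ribosomal proteins. Others mark cell types or handling that a section could hold: osteoblast and bone matrix, osteoclast, endothelial, erythroid, leukocyte and marrow, muscle and tendon, and dissociation and stress response. List genes without a matching symbol among the kept probes were not analysed here, among them Spp1, Runx2 and Pthlh. Lists were tested with limma's camera (preset correlation 0.01), camera with an estimated correlation, and fry, on ratios with outlier-flagged spots kept, adjusted over the 72 pairs of list and comparison.

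Named genes are, per comparison, the 8 highest and 8 lowest changes among called genes with a symbol, the same sign on both direct arrays and a signal well above background in all samples of the higher zone. To these come up to 4 called members of each list with the largest change, or up to 2 where none passed. Col2a1, Acan, Sox9, Fgfr3, Mki67, Ihh, Pth1r, Col10a1, Mmp13 and Cd200 are always named, and for the prehypertrophic pattern the 6 genes with the largest smaller change in each direction. The text names part of them. Of 155 called results under this rule whose gene has other kept probes, 35 have another probe of opposite sign. Below, the change of another probe is given only for Spry4. Unless stated, a change is that of the brightest probe and need not hold for the gene's other probes.

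The alternatives were no further loess, median centring, no filter on dim probes, a filter on all 12 samples, the mean of a gene's probes, no dye term, robust moderation with an intensity trend, a minimum change of 2-fold, separate-channel fits without and with the replicate number as a block, the arrays of each pair averaged as a technical dye swap, and each array left out in turn. Keeping spots with an outlier flag was added after the data were seen. Other splits of the samples were fitted with these spots kept. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.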

Results

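RNA abundance was measured in femoral growth plate cartilage of 14-day-old Swiss White mice, in 3 zones separated by microdissection of cryosections. The growth plate is the cartilage at which a long bone lengthens. Its chondrocytes divide in the proliferative zone, leave the cell cycle in the prehypertrophic zone and enlarge and mineralise their matrix in the hypertrophic zone, which borders the marrow. Each zone gave 4 samples of amplified RNA, 12 in all, hybridised as pairs of different zones on 6 arrays with the dyes exchanged between the 2 arrays of each pair. The labels do not say whether the 4 samples of a zone came from separate animals. Between 92.6% and 96.2% of the 41534 non-control spots were well above background in each sample, and the median processed signal ran from 519.6 in proliferative replicate 2 to 697.4 in proliferative replicate 4. Levels correlated at 0.958 to 0.977 between samples of 1 zone (18 pairs) and at 0.886 to 0.964 between samples of different zones (48 pairs). These correlations are across genes, which are not independent replicates, and the number of arrays limits the precision.

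Changes are log2 ratios between zones with the standard error of the limma fit (n = 4 samples per zone), and adjusted p-values cover all 27173 features tested. Since separate animals are not stated, these errors and p-values may not measure variation between mice. Gene lists were written before the data were examined. Beside the counts of members that rose, fell or did not pass stands the count adjusted over the list alone. Camera's adjusted p compares each list with all other genes, and a list is said to be called by that test unless fry is named. None of the 29 calls by camera among 72 pairs of list and comparison remained with an estimated correlation. There 4 pairs had an unadjusted p under 0.05 and the smallest adjusted p was 0.358. That version takes its p from the 3 residual degrees of freedom of the fit and so has little power. A lost call there need not reflect correlation between a list's genes. Fry, which tests whether a list's genes move one way on balance without comparing them with other genes, called 65 pairs. The median, the mean and the test differed in sign in 15 pairs, and 0 of these were called. Saturated spots compress a ratio, and this also holds in part where only some samples of a zone were saturated. Among the genes named here these were, in hypertrophic samples, Col2a1, Alpl, Timp3, Stfa1 and Ccn2 (2 each) and Mef2c and Gabarapl1 (1 each). In prehypertrophic samples they were Col2a1 (3), Acan (2) and Alpl, Aldh1a3, Mef2c, Sox9, Pth1r, Scrg1 and Bnip3 (1 each), and in proliferative samples Acan, C1qtnf3, Ucma and Mgp (2 each) and Sox9 (1).

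The first question was how the hypertrophic zone differs from the proliferative zone. Several genes that mark hypertrophic cartilage and mineral formation were far higher in the hypertrophic zone. Col10a1, the collagen that marks hypertrophic cartilage, rose by 4.74 ± 0.13 (log2), the matrix protease Mmp13 by 5.71 ± 0.26 and the phosphatase Alpl, needed for mineral formation and saturated in 2 hypertrophic samples, by 5.18 ± 0.12. Many genes of the cartilage matrix and its regulators were lower: the chondrocyte transcription factor Sox9 fell by 2.71 ± 0.04 and the small proteoglycan Fmod by 4.58 ± 0.13. With its probes averaged, Sox9 changed by -1.27. Many markers of blood, marrow and vessel cells were also higher in the hypertrophic samples, with S100a8, a neutrophil protein, at 5.39 ± 0.14 and the haemoglobin gene Hba-a1 at 3.68 ± 0.11.

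Of the 18 measured genes on the hypertrophic chondrocyte list, 11 rose, 5 fell and 2 did not pass (11 and 5 adjusted over the list alone), and the list as a whole was not called (camera adjusted p = 0.0765), though it was called higher with a gene's probes averaged (0.0447) and without the dye term (0.0367). Ibsp, an acidic bone matrix protein, rose by 5.64 ± 0.41, with its spots saturated in all 4 hypertrophic samples, which compresses the ratio. Cd200, a surface glycoprotein, rose by 3.69 ± 0.13. The study concerns the sorting of growth plate chondrocytes and chose Cd200 itself, so its rise is not independent evidence. The mineralisation and phosphate handling list had 14 of 18 members higher and 2 lower (14 and 2 adjusted over the list alone), with camera adjusted p = 0.00107 and adjusted p = 0.358 with an estimated correlation. Phex, an endopeptidase of phosphate regulation, rose by 6.05 ± 0.11 and the carbonic anhydrase Car2 by 3.96 ± 0.13. Which cell types carry the rises in this paragraph was not tested. Among the single genes with the largest rises were the transcription factor Irx5 (7.59 ± 0.22), the prostaglandin synthase Ptgs2 (7.35 ± 0.37), the kinase Plk2 (6.28 ± 0.20), the natriuretic peptide clearance receptor Npr3 (6.0 ± 0.43) and the proteoglycan Srgn (5.91 ± 0.12). Aldh1a3, a retinoic acid synthesising enzyme, rose by 6.59 ± 0.41 and was likewise saturated in all 4 hypertrophic samples. Spry4, an inhibitor of receptor tyrosine kinase signalling, was at least 30.6-fold higher by its brightest probe, which was not well above background in any proliferative sample, but its other probe changed by 0.17 and the mean of its probes by 2.98.

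Of the 24 chondrocyte matrix genes, 18 fell, 1 rose and 5 did not pass (18 lower and 1 higher adjusted over the list alone), with camera adjusted p = 8.78e-06 and adjusted p = 0.358 with an estimated correlation. The largest falls on this list were those of Fmod, of Ucma, a small cartilage matrix protein (-4.31 ± 0.39, saturated in 2 proliferative samples), of Cnmd, which inhibits vessel growth into cartilage (-3.76 ± 0.16), and of Sox5, a partner of Sox9 (-3.54 ± 0.07). The value for Sox5 is that of its brightest probe, and with its probes averaged it changed by -1.07. The receptor Fgfr3, which restrains chondrocyte division, fell by 1.03 ± 0.04. Col2a1, the main cartilage collagen, changed by -0.26 ± 0.19 and did not pass (adjusted p = 0.30), but its spots were saturated in all 4 proliferative and 2 hypertrophic samples, which compresses its ratio. The 1 member that passed as higher was the proteoglycan Acan (0.32 ± 0.09, adjusted p = 0.0376), saturated in 2 proliferative and all 4 hypertrophic samples. It did not pass when array 1, 2, 4, 5 or 6 was left out (adjusted p 0.052 to 0.149), nor without loess (0.0556), without the dye term (0.281), with robust moderation (0.0651) or with each pair of arrays averaged (0.126). Outside the lists, large falls were those of the secreted protein C1qtnf3 (-6.33 ± 0.14, saturated in 2 proliferative samples), the growth factor Gdf10 (-5.98 ± 0.19) and the neurotrophin receptor Ntrk2 (-5.53 ± 0.14).

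Cell cycle genes were split between these zones: of 36 measured, 12 rose, 19 fell and 5 did not pass (12 higher and 19 lower adjusted over the list alone), and the list was not called (camera adjusted p = 0.303). Mki67, present in cycling cells, was 0.48 ± 0.09 higher (adjusted p = 0.011), a call that ended without array 2 (0.46, adjusted p = 0.0634) and with each pair of arrays averaged (0.0661), while the mitotic kinase Aurkb fell by 1.45 ± 0.06. Of 15 cell cycle inhibitors, 8 rose, 3 fell and 4 did not pass (8 and 4 adjusted over the list alone), including Cdkn1a (3.41 ± 0.07) and Gadd45b (3.09 ± 0.03). That list's camera adjusted p was 0.0426, with adjusted p = 0.358 with an estimated correlation, and it rose to 0.0594 without array 1, 0.0523 without array 6, 0.0509 with the filter on all 12 samples and 0.0559 with each pair of arrays averaged. Immediate-early and stress genes rose in 15 of 18 cases and fell in 2 (15 and 2 adjusted over the list alone), with camera adjusted p = 1.47e-04 and adjusted p = 0.358 with an estimated correlation. Examples are the transcription factors Egr1 (3.95 ± 0.11) and Fos (3.70 ± 0.04), while the heat shock gene Hspa1b fell by 3.06 ± 0.08.

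Markers of other cell types moved with these groups. Of 19 leukocyte and marrow genes, 15 rose, 3 fell and 1 did not pass (16 and 3 adjusted over the list alone), with camera adjusted p = 2.21e-04 and adjusted p = 0.358 with an estimated correlation. All 6 erythroid genes rose (6 adjusted over the list alone), with camera adjusted p = 0.00237 and adjusted p = 0.474 with an estimated correlation. Of 14 endothelial genes, 9 rose, 0 fell and 5 did not pass (9 adjusted over the list alone), with camera adjusted p = 0.00407 and adjusted p = 0.477 with an estimated correlation. Camp, a neutrophil granule peptide, rose by 5.36 ± 0.14, Hemgn, an erythroid nuclear protein, by 4.59 ± 0.07, and the vessel genes Kdr and Emcn by 3.66 ± 0.08 and 3.43 ± 0.11. The osteoclast list had 7 of 13 genes higher and 3 lower (7 and 3 adjusted over the list alone) and was not called (0.158), except with a gene's probes averaged (0.0139). Its protease Mmp9 rose by 4.48 ± 0.13. The osteoblast and bone matrix list had 7 of 13 higher and 4 lower (8 and 4 adjusted over the list alone) and was not called (0.20). Muscle and tendon genes rose in 5, fell in 2 and did not pass in 5 of 12 cases (5 and 2 adjusted over the list alone), and the list was not called (0.531).

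Energy and turnover genes also differed. Glycolysis and hypoxia genes fell in 16 of 21 cases and rose in 3 (17 and 3 adjusted over the list alone), with camera adjusted p = 7.6e-04 and adjusted p = 0.358 with an estimated correlation. The pyruvate dehydrogenase kinase Pdk1 fell by 2.78 ± 0.05 and the carbonic anhydrase Car12 by 2.54 ± 0.05. Oxidative phosphorylation genes rose in 13 of 19 cases and fell in 4 (13 and 4 adjusted over the list alone), with camera adjusted p = 0.020 and adjusted p = 0.358 with an estimated correlation. That call ended without the dye term (0.0623). Lysosome and autophagy genes rose in 11 of 16 cases and fell in 4 (11 and 4 adjusted over the list alone), with camera adjusted p = 0.0131 and adjusted p = 0.358 with an estimated correlation. Examples are the autophagosome proteins Gabarapl1 (2.5 ± 0.03) and Map1lc3b (2.38 ± 0.03). Ribosomal protein genes fell in 10 of 18 cases and rose in 0 (10 adjusted over the list alone), with camera adjusted p = 0.0426 and adjusted p = 0.474 with an estimated correlation. Rps19 fell by 1.09 ± 0.04, and this list's p was 0.0594 without array 1, 0.0659 without array 3 and 0.103 without array 6. It was 0.0628 without loess, 0.0638 with median centring and 0.055 with the filter on all 12 samples.

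In all, 16000 of 27173 features differed (7662 higher and 8338 lower in the hypertrophic zone), 4023 of them at least 2-fold (2444 higher, 1579 lower). Of the called features, 91.4% had the same sign on both arrays that carried these zones together. Those arrays are part of the fit that makes the calls, so this share, here and in the later comparisons, is no independent check. The median standard error was 0.0511. Averaging a gene's probes moved the log2 change by over 1.5 times in 10 of the 64 called results that the rule for naming genes gives, none of which turned: Sox9 (-1.27), Sox5 (-1.07), Spry4 (2.98), Ihh (2.58), Ptch1 (-1.435), Car12 (-1.36), Creb3l2 (-2.16), Bmp6 (1.55), Hemgn (3.02) and Hspa1b (-1.55).

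**Figure D1:**
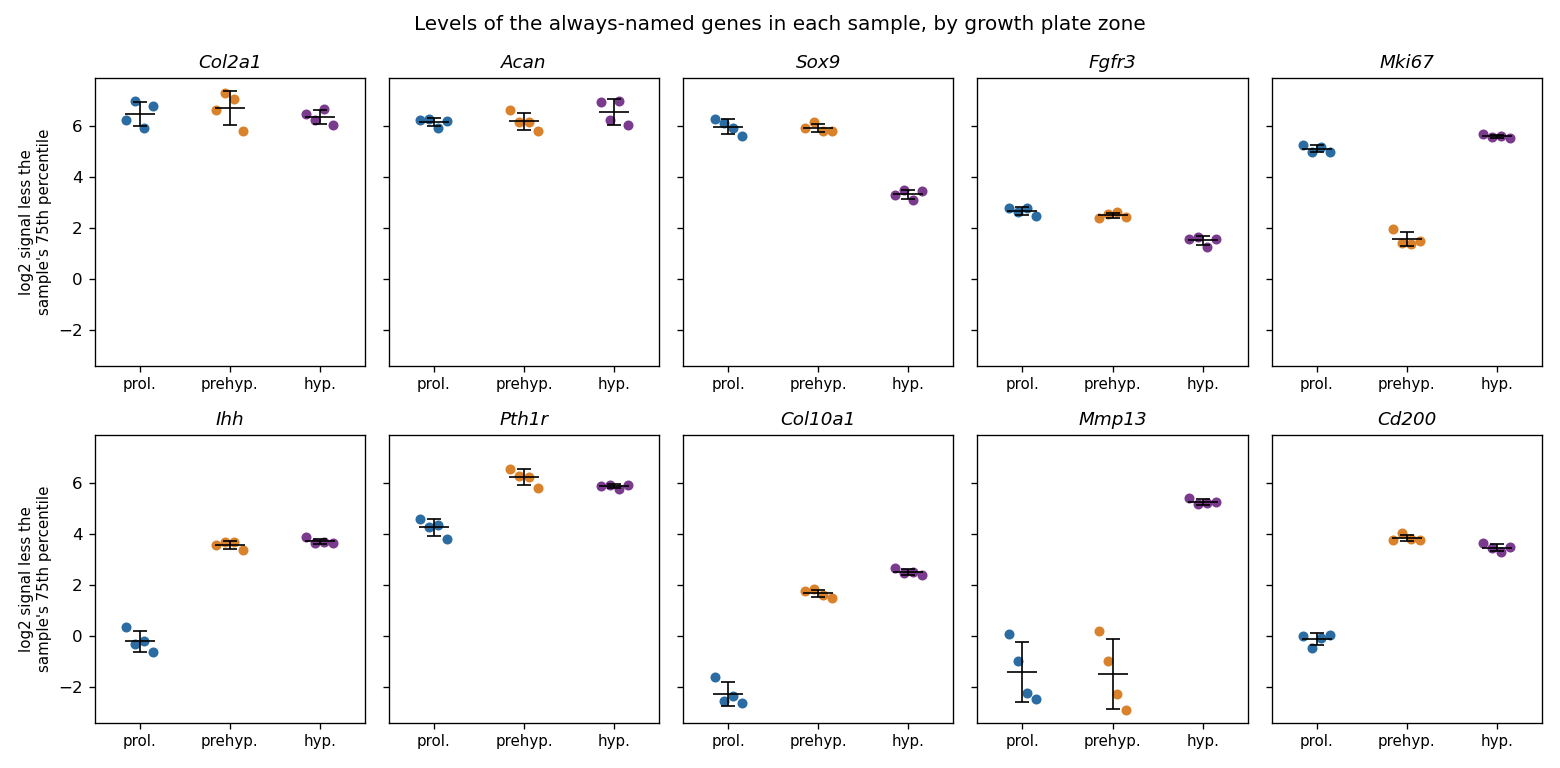
Level of each always-named gene in each sample, as log2 signal less the sample's 75th percentile. Points are samples, the long bar is the mean and the error bar the SD of the 4 samples of a zone. Col10a1, Ihh and Cd200 sit higher in all prehypertrophic and hypertrophic samples than in any proliferative sample, Mmp13 is high in the 4 hypertrophic samples, and Mki67 is low in the 4 prehypertrophic samples.

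The second question was what changes as chondrocytes stop dividing and become prehypertrophic. Cell cycle genes fell together from the proliferative to the prehypertrophic zone: 34 of 36 fell, 0 rose and 2 did not pass (34 adjusted over the list alone). Aurkb fell by 5.76 ± 0.06 and Mki67 by 3.59 ± 0.09. Over the same step Ihh, the hedgehog signal of prehypertrophic cells, rose by 3.83 ± 0.10, Col10a1 by 3.99 ± 0.13 and Alpl by 4.99 ± 0.12. Sox9 (-0.00 ± 0.04, adjusted p = 0.95) and Fgfr3 (-0.10 ± 0.04, adjusted p = 0.093) did not pass, and neither did Mmp13 (-0.15 ± 0.26, adjusted p = 0.69), though with a gene's probes averaged Sox9 passed as higher (0.24, adjusted p = 0.00707). Fgfr3 passed as lower in the separate-channel fit (-0.10, adjusted p = 0.0209) and with the replicate number as a block in that fit (-0.12, adjusted p = 0.0449). The lists of leukocyte, erythroid and endothelial markers were not called between these zones.

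The cell cycle list had camera adjusted p = 5.57e-17 and adjusted p = 0.358 with an estimated correlation. The motility receptor Hmmr, which acts on the mitotic spindle, fell by 4.00 ± 0.05 and the spindle protein Nusap1 by 3.91 ± 0.06. With probes averaged, these changes were -2.395 and -2.36. Among single genes outside the list, the cytokinesis factor Ect2 fell by 5.11 ± 0.16, the mitotic kinase Pbk by 4.77 ± 0.04 and the spindle protein Spag5 by 4.48 ± 0.36. With probes averaged, Ect2 changed by -2.53 and Spag5 by -2.26. Cell cycle inhibitors rose in 8 of 15 cases and fell in 5 (8 and 5 adjusted over the list alone), and the list was not called (camera adjusted p = 0.536). The retinoblastoma gene Rb1 rose by 2.99 ± 0.02 and Cdkn1a by 2.81 ± 0.07.

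Hypertrophic chondrocyte genes rose in 11 of 18 cases, fell in 4 and did not pass in 3 (12 and 4 adjusted over the list alone), with camera adjusted p = 0.0131 and adjusted p = 0.358 with an estimated correlation. Ibsp rose by 4.29 ± 0.41 and Cd200, which the study chose, by 3.94 ± 0.13. The sphingomyelin synthase Sgms2 rose by 3.12 ± 0.04. Genes of hedgehog and PTHrP signalling went both ways, with 8 of 19 higher and 6 lower (8 and 6 adjusted over the list alone) and no call (0.638). With Ihh rose the PTHrP receptor Pth1r (1.94 ± 0.06) and the transcription factor Mef2c (2.30 ± 0.06), whereas Ptch1, the hedgehog receptor, and Hhip, a hedgehog-binding inhibitor, fell by 3.40 ± 0.18 and 2.82 ± 0.09. The mineralisation list had 8 of 18 higher and 3 lower (10 and 3 adjusted over the list alone) and was not called (0.0759). Mgp, an inhibitor of calcification, fell by 2.94 ± 0.10 and Phex rose by 5.11 ± 0.11. Of the chondrocyte matrix genes 11 of 24 fell and 1 rose (11 lower and 2 higher adjusted over the list alone), without a call (0.0642), though the list was called lower without the dye term (0.0237) and without array 2 (0.0451). Sox5 fell by 2.41 ± 0.07 by its brightest probe and changed by -0.788 with its probes averaged. Among the largest single rises, beside Phex and Alpl, were those of Aldh1a3 (6.53 ± 0.41), Irx5 (5.47 ± 0.22), the membrane glycoprotein Prom1 (5.25 ± 0.27), the annexin Anxa3 (4.98 ± 0.07) and the glycine-cleaving enzyme Gldc (4.77 ± 0.10).

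Ribosomal protein genes fell in 11 of 18 cases and rose in 0 (11 adjusted over the list alone), with camera adjusted p = 8.1e-04 and adjusted p = 0.358 with an estimated correlation. Rps9 fell by 0.72 ± 0.02. Lysosome and autophagy genes rose in 12 of 16 cases and fell in 3 (12 and 4 adjusted over the list alone), with camera adjusted p = 0.00713 and adjusted p = 0.358 with an estimated correlation, led by Gabarapl1 (1.91 ± 0.03). Oxidative phosphorylation genes fell in 10 of 19 cases and rose in 4 (11 and 4 adjusted over the list alone), with camera adjusted p = 0.0414 and adjusted p = 0.419 with an estimated correlation. Sdhb, a subunit of succinate dehydrogenase, fell by 0.60 ± 0.03. Glycolysis and hypoxia genes fell in 11 of 21 cases and rose in 4 (11 and 4 adjusted over the list alone), with camera adjusted p = 0.0467 and adjusted p = 0.534 with an estimated correlation. The oxygen sensor Egln3 fell by 1.99 ± 0.08. Without array 1, 4 or 6 the oxidative phosphorylation p was 0.0594, 0.0511 and 0.0723 and the glycolysis p 0.060, 0.0602 and 0.188. With the filter on all 12 samples they were 0.0509 and 0.0572, with each pair of arrays averaged 0.0638 and 0.0656. The first was 0.0736 with a gene's probes averaged and the second 0.063 without the dye term.

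Of the marker lists, leukocyte and marrow genes rose in 3 and fell in 2 of 19 cases (3 and 2 adjusted over the list alone, 0.42), erythroid genes rose in 0 and fell in 1 of 6 (0 and 1 adjusted over the list alone, 0.633), and endothelial genes rose in 2 and fell in 2 of 14 (2 and 2 adjusted over the list alone, 0.99). Osteoclast genes rose in 2 and fell in 3 of 13 cases (2 and 3 adjusted over the list alone, 0.851), osteoblast and bone matrix genes rose in 6 and fell in 4 of 13 (6 and 5 adjusted over the list alone, 0.551), and muscle and tendon genes rose in 2 and fell in 2 of 12 (2 and 2 adjusted over the list alone, 0.99). Stress genes rose in 10 and fell in 3 of 18 cases (10 and 3 adjusted over the list alone, 0.188), and Fos rose by 2.66 ± 0.04. None of these 7 lists was called.

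In all, 12483 features differed (6365 higher and 6118 lower in the prehypertrophic zone), 2087 at least 2-fold (889 higher, 1198 lower), with the same sign on both direct arrays for 96.1% of the called. The count was 8768 without array 5 (4138 higher, 4630 lower) and 7730 when the 2 arrays of each pair were averaged as a technical dye swap (3433 higher, 4297 lower). Averaging a gene's probes moved 15 of the 58 called results that the naming rule gives by over 1.5 times, and none turned: Ect2 (-2.53), Spag5 (-2.26), Hmmr (-2.395), Nusap1 (-2.36), Ptch1 (-1.75), Ihh (2.43), Sox5 (-0.788), Mmp14 (-1.22), Creb3l2 (-0.815), Bmp6 (1.28), Epb42 (-0.365), Hspa1b (-1.18), Prom1 (3.03), Klf8 (1.34) and Epb41l3 (2.17).

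**Figure D2:**
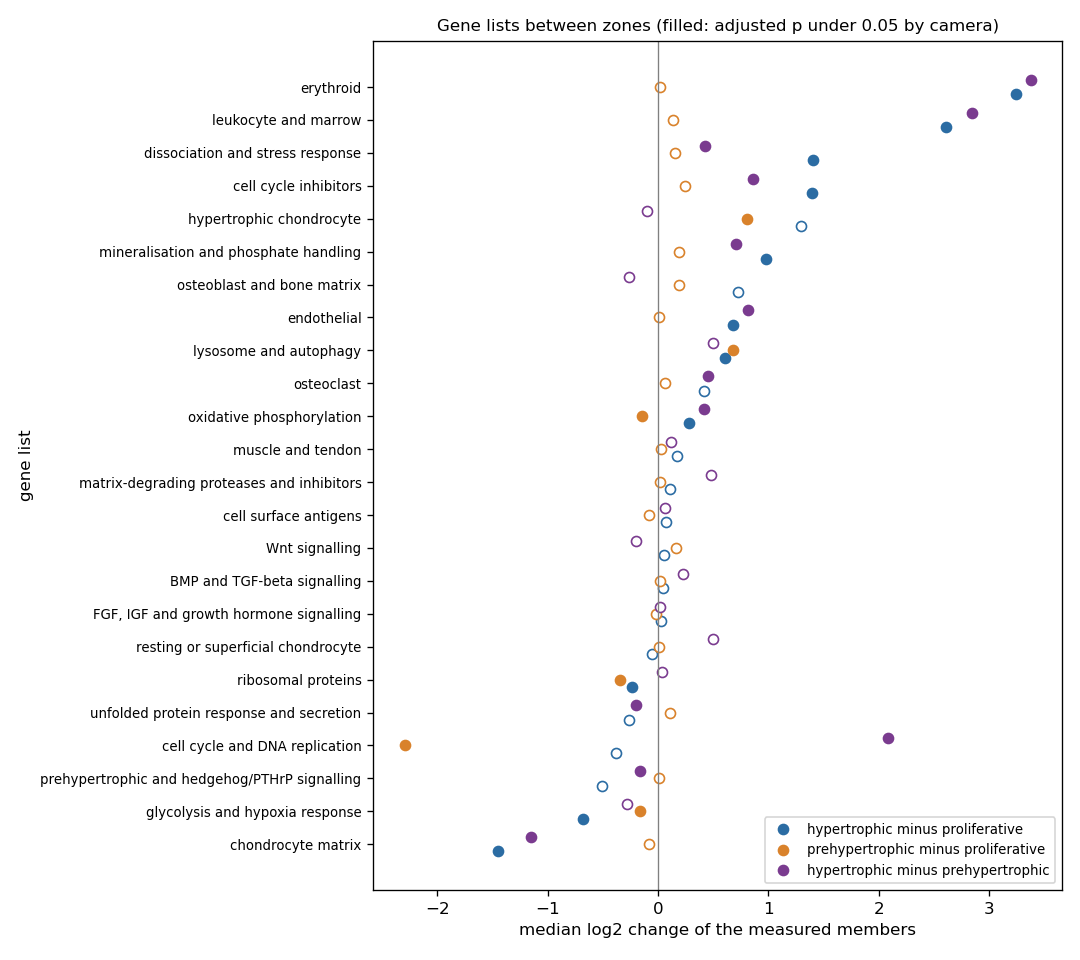
Median log2 change of the measured members of each of the 24 gene lists in the 3 comparisons between zones. Each point is 1 list in 1 comparison, filled where camera's adjusted p is under 0.05 with the preset correlation and open where it is not. The cell cycle list lies at -2.30 for prehypertrophic minus proliferative and at 2.08 for hypertrophic minus prehypertrophic.

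The third question was what separates hypertrophic from prehypertrophic cartilage. Mmp13 rose by 5.86 ± 0.26 between them, while Col10a1 rose by 0.75 ± 0.13, and Ihh (0.08 ± 0.10, adjusted p = 0.54) and Cd200 (-0.25 ± 0.13, adjusted p = 0.18) did not pass, though Cd200 passed as lower without array 2 (-0.35, adjusted p = 0.0324) and in the separate-channel fit (-0.26, adjusted p = 0.0318). The level of Mmp13 was 0.20 and -1.01 (log2, relative to the sample's 75th percentile) in the prehypertrophic samples that shared an array with a hypertrophic sample and -2.31 and -2.90 in the other 2. Sox9 fell by 2.70 ± 0.04 and most cartilage matrix genes fell with it. With its probes averaged, Sox9 changed by -1.51. Cell cycle genes rose again, with Mki67 at 4.07 ± 0.09, and leukocyte, erythroid and endothelial markers rose over the same step, with S100a8 at 4.94 ± 0.14 and Kdr at 3.57 ± 0.08.

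Of the chondrocyte matrix genes, 19 of 24 fell, 1 rose and 4 did not pass (21 lower and 1 higher adjusted over the list alone), with camera adjusted p = 7.89e-07 and adjusted p = 0.358 with an estimated correlation. Scrg1 fell by 3.08 ± 0.29 and Cnmd by 2.81 ± 0.16. The 1 that rose was Acan (0.32 ± 0.09, adjusted p = 0.0381), which did not pass without array 2, 4, 5 or 6 (0.0887 to 0.135), without loess (0.0547), without the dye term (0.283), with robust moderation (0.066) or with each pair of arrays averaged (0.128). Fgfr3 fell by 0.93 ± 0.04. Of the hedgehog and PTHrP signalling genes 10 of 19 fell and 1 rose (10 and 1 adjusted over the list alone), with camera adjusted p = 0.0414 and adjusted p = 0.358 with an estimated correlation. The transcription factor Foxa3 fell by 2.09 ± 0.06 and the hedgehog co-receptor Cdon by 1.82 ± 0.03. That list's p was 0.0675 without array 1, 0.0652 without array 2 and 0.0523 without array 6. It was 0.0567 without loess, 0.0532 with median centring and 0.0661 with each pair of arrays averaged. Hypertrophic chondrocyte genes went both ways, 6 of 18 higher and 7 lower (6 and 7 adjusted over the list alone), without a call (0.85). The connective tissue growth factor Ccn2 rose by 3.19 ± 0.08 and the vessel growth factor Vegfa by 2.36 ± 0.16, while Sgms2 fell by 3.29 ± 0.04. Mineralisation genes rose in 12 of 18 cases and fell in 3 (13 and 4 adjusted over the list alone), with camera adjusted p = 0.0147 and adjusted p = 0.358 with an estimated correlation. The pyrophosphate transporter Ank rose by 3.23 ± 0.07, Car2 by 3.75 ± 0.13, and Mgp by 3.59 ± 0.10 with its spots saturated in all 4 hypertrophic samples.

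Cell cycle genes rose in 35 of 36 cases and fell in 1 (35 and 1 adjusted over the list alone), with camera adjusted p = 8.66e-13 and adjusted p = 0.358 with an estimated correlation. Aurkb rose by 4.31 ± 0.06 and the replication helicase subunit Mcm3 by 3.66 ± 0.06. Cell cycle inhibitors rose in 11 of 15 cases and fell in 4 (11 and 4 adjusted over the list alone), with camera adjusted p = 0.0272 and adjusted p = 0.358 with an estimated correlation. Leukocyte and marrow genes rose in 14 of 19 cases and fell in 1 (14 and 1 adjusted over the list alone), with camera adjusted p = 3.64e-04 and adjusted p = 0.358 with an estimated correlation. All 6 erythroid genes rose (6 adjusted over the list alone) and so did 11 of 14 endothelial genes, with 1 lower (11 and 1 adjusted over the list alone). Both lists had camera adjusted p = 0.00155 and adjusted p = 0.474 with an estimated correlation. Camp rose by 5.11 ± 0.14, the protease inhibitor Stfa1 by 4.98 ± 0.08, the red cell membrane protein Epb42 by 4.36 ± 0.14 and Emcn by 3.30 ± 0.11. Osteoclast genes rose in 8 of 13 cases and fell in 2 (8 and 2 adjusted over the list alone), with camera adjusted p = 0.0426 and adjusted p = 0.600 with an estimated correlation. The bone-resorbing protease Ctsk rose by 3.95 ± 0.18 and Mmp9 by 4.41 ± 0.13. The osteoclast p was 0.060 without array 1, 0.0535 without array 2 and 0.0668 without array 6, and 0.0509 with the filter on all 12 samples. Stress genes rose in 12 of 18 cases and fell in 1 (13 and 1 adjusted over the list alone), with camera adjusted p = 0.00107 and adjusted p = 0.358 with an estimated correlation, and Egr1 rose by 5.32 ± 0.11.

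Oxidative phosphorylation genes rose in 15 of 19 cases and fell in 2 (16 and 2 adjusted over the list alone), with camera adjusted p = 7.6e-04 and adjusted p = 0.358 with an estimated correlation. Ndufa4 rose by 1.02 ± 0.02. Glycolysis and hypoxia genes fell in 10 of 21 cases and rose in 4 (11 and 4 adjusted over the list alone), without a call (0.0816), except without the dye term (0.0451). Car12 fell by 2.86 ± 0.05 and the mitophagy receptor Bnip3 by 2.58 ± 0.03. Genes of the unfolded protein response and secretion fell in 12 of 21 cases and rose in 4 (12 and 4 adjusted over the list alone), with camera adjusted p = 0.0414 and adjusted p = 0.523 with an estimated correlation. Creb3l2, a transcription factor of the secretory pathway, fell by 1.72 ± 0.04. This list's p was 0.0594 without array 1, 0.0509 with the filter on all 12 samples and 0.106 with a gene's probes averaged. Lysosome and autophagy genes rose in 9 of 16 cases and fell in 5 (9 and 5 adjusted over the list alone, 0.166), ribosomal protein genes rose in 4 and fell in 1 of 18 (4 and 1 adjusted over the list alone, 0.551), osteoblast and bone matrix genes rose in 5 and fell in 7 of 13 (6 and 7 adjusted over the list alone, 0.99), and muscle and tendon genes rose in 3 and fell in 2 of 12 (3 and 2 adjusted over the list alone, 0.638). These 4 lists were not called. Among single genes, Spry4 was at least 28.3-fold higher by its brightest probe while its other probe changed by -0.64, and Plk2 rose by 5.54 ± 0.20, while the keratan sulphate proteoglycan Omd fell by 4.71 ± 0.03, C1qtnf3 by 4.48 ± 0.14, the inositol transporter Slc5a3 by 4.23 ± 0.03 and the glutamate transporter Slc1a3 by 3.59 ± 0.06.

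In all, 15713 features differed (7597 higher and 8116 lower in the hypertrophic zone), 2826 at least 2-fold (1986 higher, 840 lower), with the same sign on both direct arrays for 95.7% of the called. Averaging a gene's probes moved 11 of the 57 called results that the naming rule gives by over 1.5 times, and none turned: Spry4 (2.54), Sox9 (-1.51), Vegfa (1.425), Nusap1 (2.11), Ect2 (2.08), Car12 (-1.61), Hemgn (3.17), Epb42 (2.80), Prom1 (-1.53), Klf8 (-1.455) and Epb41l3 (-1.77).

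The prehypertrophic zone lies between the others, which raised the question of which genes are highest or lowest there. Many cell cycle genes were lowest in the prehypertrophic zone. By the brightest probe of each gene, Ect2, Aurkb and Nusap1 led the genes that fell and rose again. With them were the ribonucleotide reductase subunit Rrm2 (-3.65 ± 0.13, then 3.64 ± 0.13), the imprinted gene Mest (-3.75 ± 0.05, then 3.64 ± 0.05) and Mki67. With probes averaged, Ect2 changed by -2.53 and then 2.08, and Nusap1 by -2.36 and then 2.11. Highest there were Sgms2 and Prom1 (5.25 ± 0.27, then -2.97 ± 0.27), the transcription factor Klf8 (2.71 ± 0.03, then -2.77 ± 0.03), the cytoskeletal protein Epb41l3 (3.82 ± 0.09, then -2.69 ± 0.09) and the kinase Map3k8 (2.91 ± 0.18, then -2.44 ± 0.18). With a gene's probes averaged, the changes of Prom1 were 3.03 and -1.53, those of Klf8 1.34 and -1.455 and those of Epb41l3 2.17 and -1.77. The prokineticin receptor Prokr2 was at least 9.98-fold higher in the prehypertrophic than in the proliferative zone, where it was not well above background in any sample, and then fell by 3.25 ± 0.61. Its first change did not pass without array 6 (adjusted p = 0.127), and its second did not pass without array 3, 4 or 6 (adjusted p 0.0596, 0.0931 and 0.115). Neither passed with each pair of arrays averaged (0.0646 and 0.0591).

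Passing both steps in opposite directions were 2978 features highest and 2907 lowest in the prehypertrophic zone, 5885 in all, of which 536 changed at least 2-fold at both steps (133 highest, 403 lowest). Lists drawn independently would share 1901 and 1710. Both steps use the same prehypertrophic samples, whose errors push the steps in opposite directions. In 20 simulations with no true change the highest count was 0. With nothing changed, the adjustment lets hardly any feature pass either step, so these simulations cannot show how far the shared error raises the counts. The share of this error among genes that truly change was not simulated. Without array 5 the counts were 1735 highest and 2197 lowest, averaging each pair of arrays gave 1180 highest and 1938 lowest, 3118 in all, and leaving out the dye term gave 1834 highest and 2354 lowest. A further 2096 features rose over both steps and 1846 fell over both, where independent lists would share 1780 and 1827.

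**Figure D3:**
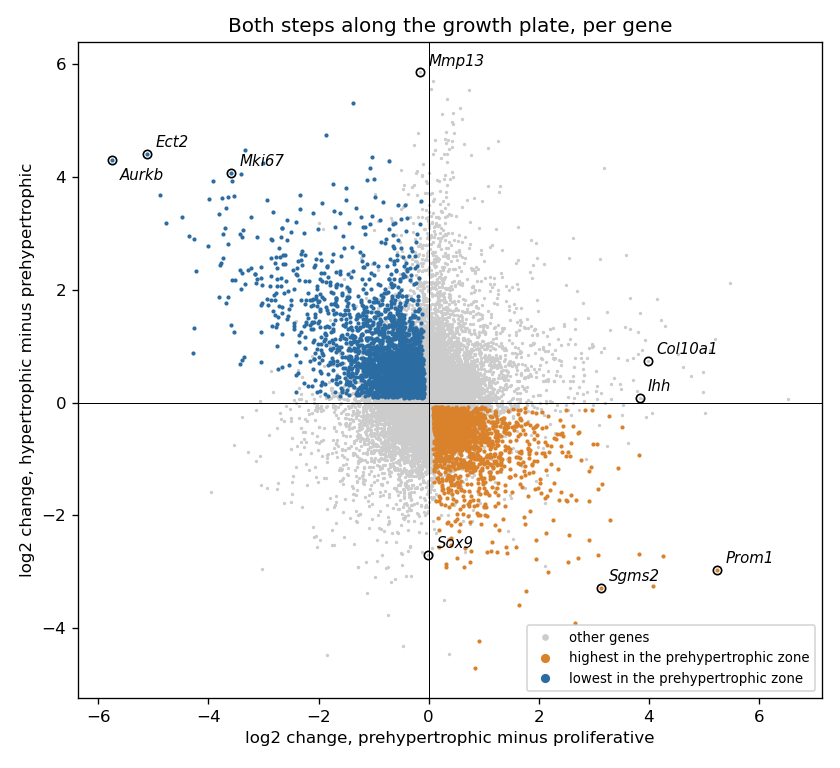
Log2 change from the proliferative to the prehypertrophic zone (horizontal axis) against that from the prehypertrophic to the hypertrophic zone (vertical axis), 1 point per feature tested. Orange points passed as highest and blue points as lowest in the prehypertrophic zone. Aurkb, Ect2 and Mki67 lie at the upper left, Prom1 and Sgms2 at the lower right, Ihh and Col10a1 near the horizontal axis, and Mmp13 and Sox9 near the vertical axis.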

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

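The tests of the leukocyte and erythroid pattern and of the cell cycle pattern below were chosen after the results were seen, as was the test of blood and marrow RNA in the pattern by shared array. The splits of the samples and the other tests of that pattern were not.

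In 3 of 63 groups of 4 samples, 1 sample lay far from the other 3, and chance alone does this in about 1 of 20 groups. Hypertrophic replicate 2 had 10.3% of its spots marked as outliers by the scanner software, against 0.330% to 1.40% in the other hypertrophic samples. Prehypertrophic replicate 1 had an Mki67 level of 1.97, against 1.37 to 1.47 in the other prehypertrophic samples. Prehypertrophic replicate 4 had a mean level of the osteoblast and bone matrix genes of 2.02, against 2.24 to 2.26.

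The splits of the samples were meant to ask whether chance could give the 4 counts. They cannot decide it, because the other splits mix zones within a group, so the zone difference enters the residual spread. Few calls there follow from that mixing, whatever the source of the real counts. The labels also do not say whether the 4 samples of a zone came from separate animals. Of 34 splits of the 8 samples of 2 zones that could be fitted (1 could not), 1, the real one, gave as many called features in each comparison, with outlier-flagged spots kept. The real counts were 15815 (hypertrophic minus proliferative), 12281 (prehypertrophic minus proliferative) and 15489 (hypertrophic minus prehypertrophic), and the highest of the other splits were 0, 1 and 0. For features highest or lowest in the prehypertrophic zone, 1 of 100 regroupings of the 12 samples, the real one, gave as many. The real count was 5787 and the highest other 54.

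Leukocyte and erythroid genes were higher in the hypertrophic samples than in both other zones. A single array or dye is excluded, since the lowest of the 4 array means was 2.26 (log2, standard error 0.33 over members). A lower share of chondrocytes that raises every other cell type alike stays open. From prehypertrophic to hypertrophic the 12 muscle and tendon genes changed by -0.02 on average (SD 1.03). The 25 leukocyte and erythroid genes changed by 2.44 (SD 1.82, 2-sided permutation p = 0.00018 over genes, which are not independent replicates). This cannot decide it, because the muscle and tendon genes had low mean levels in every sample, from -2.19 to -1.79. Cells that bear them may be absent, and absent cells cannot rise. Blood and marrow cells in the hypertrophic samples stay a candidate explanation: 80% of the measured members (20 of 25) were called higher than in both other zones, which lay between the bounds set for and against it. All 25 are also well above background in every other sample, none is on another list, S100a8 reached a level of 5.95 and Hba-a1 5.31 in the hypertrophic samples, no sort or gate removed such cells, and expression in hypertrophic chondrocytes themselves was not tested.

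Cell cycle genes were lowest in the prehypertrophic zone and high again in the hypertrophic samples. Proliferative chondrocytes carried into the hypertrophic samples are excluded as the whole source: 33 cell cycle genes that had fallen at least 1.5-fold regained a median of 86.7% of the fall, while 8 chondrocyte matrix or resting genes had a median of -115%, 7 of them falling again (exact rank-sum p = 6.83e-05, 2-sided). A single array or dye is excluded, since the highest of the 4 array means, prehypertrophic over the other sample, was -2.01 (log2). Dividing blood and marrow cells in the hypertrophic samples may be the source of the second rise (median 2.08), and this cannot be told apart from division of chondrocytes there, because all 4 hypertrophic samples also held more leukocyte and erythroid RNA.

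Genes of the hypertrophic zone read higher in samples of the other zones that shared an array with a hypertrophic sample, by a median of 0.32 in proliferative and 0.34 in prehypertrophic samples (434 genes), and Mmp13 read 0.06 and -0.99 in such proliferative samples against -2.26 and -2.47 in the other 2. The further loess step is excluded as the source, since 101% of the difference was left without it. The scanner software's own dye normalization within each array was present in both cases, so that step was not tested. Blood and marrow RNA in those samples is a candidate explanation: the 15 leukocyte and erythroid genes among the 434 differed by a median of 1.12 in proliferative and 1.09 in prehypertrophic samples, against 0.308 and 0.328 for the 411 genes on no list of blood, vessel or osteoclast markers (rank-sum p at most 9.01e-05, 2-sided). The test first planned, on genes of the proliferative zone in hypertrophic samples (0.331), was dropped, since blood RNA in the other samples predicts nothing for them. Whether blood and marrow RNA gives the whole difference was not tested, nor whether genes with a larger ratio between zones would differ more under any explanation. Signal of 1 channel adding to the other stays open: it could give the differences of the proliferative genes (92 genes, 0.14 and 0.33), but the 16 genes of the prehypertrophic zone read no higher, with -0.16 and -0.05. The bound set against it was met by these 16 genes, but both values lay inside the range of random sets of 16 genes, so that they decide nothing.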

How the results depend on the processing

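The alternative that keeps spots with an outlier flag was chosen after the data were seen, and all others before. It gave 15815, 12281 and 15489 called features, 5787 highest or lowest in the prehypertrophic zone and 29 gene lists. Requiring a change of at least 2-fold gave 4023 (hypertrophic minus proliferative), 2087 (prehypertrophic minus proliferative), 2826 (hypertrophic minus prehypertrophic) and 536 (highest or lowest in the prehypertrophic zone), by construction fewer. Averaging the arrays of each pair as a technical dye swap gave 7730 for prehypertrophic minus proliferative and 3118 for highest or lowest, with fewer ratios in the fit. Camera with an estimated correlation called 0 lists and fry 65. For cell cycle inhibitors, a higher correlation within the list is not the source of the lost calls. Their estimated correlation was -0.0604, below the preset one. Their adjusted p still went from 0.0426 to 0.358 (hypertrophic minus proliferative) and from 0.0272 to 0.358 (hypertrophic minus prehypertrophic). With an estimated correlation, camera takes its p from the 3 residual degrees of freedom of the fit, which leaves little power. With the preset correlation it does not. How much of the loss came from this or from the adjustment over all pairs was not tested. With each array left out in turn, the counts ran from 12935 to 15065, from 8768 to 11331, from 12344 to 15057 and from 3932 to 5164, and 22 to 29 lists were called. Under the other alternatives every count stayed within 1.5 times its value. The fit with the replicate number as a block gave 17072, 13332, 15292 and 5961. Across arrays the labels' numbers showed no clear pairing: of 12 same-number pairs, the 4 on 1 array correlated at 0.451 to 0.575 and the other 8 at -0.249 to 0.266. On 1 array with different numbers, hypertrophic replicate 3 and prehypertrophic replicate 1 correlated at 0.316. Hypertrophic replicate 4 and prehypertrophic replicate 2 did so at 0.265. These join other zones than the 4, so number and zone pair cannot be told apart within arrays.

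Averaging a gene's probes called 273, 157 and 233 features in the opposite direction, in the order of the 3 comparisons above, and every other alternative at most 2. Among named genes, signs turned only in changes that had not passed. For prehypertrophic minus proliferative, averaging a gene's probes gave -0.0088 for Col2a1, 0.24 for Sox9 (adjusted p = 0.00707) and 0.0875 for Fgfr3. With each array left out in turn, Col2a1 ran from -0.0135 (without array 5) to 0.45 (without array 6, which passed), Acan from -0.0647 to 0.0764 (above 0 without array 5, 0.062, or 6), Sox9 from -0.0297 to 0.0244 (above 0 without array 1, 0.0181, or 3) and Mmp13 from -0.38 to 0.26 (above 0 without array 6). For hypertrophic minus prehypertrophic, Ihh ran from -0.0659 (without array 3) to 0.16. The causes were not tested. Of 3190 combinations of named result and alternative, 3142 kept direction and side of the threshold, 31 no longer passed, 7 newly passed and 10 changed sign.

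Not run were no background correction and normexp with an offset of 0, since the files used here hold only processed signal, the value table, whose columns hold other samples' values, and a term for slide or scan date, since the files give 1 date and the 1 slide that stands apart is array 6. Saturation compresses the ratios of the brightest genes, such as Col2a1, and dim genes such as Spry4 have only lower bounds.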

Other observations

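Members of the BMP and TGF-beta, Wnt and FGF lists went both ways. Camera called none of these lists in any comparison, while fry called each of them in each (adjusted p 6.48e-04 to 0.0102). From the proliferative to the hypertrophic zone, 9 of 25 BMP and TGF-beta genes rose and 8 fell (9 and 8 adjusted over the list alone, camera adjusted p = 0.615), with Tgfb3 at 3.23 ± 0.06 and Bmp6 at 2.84 ± 0.09 while Bmp7 fell by 2.71 ± 0.11. From proliferative to prehypertrophic 8 rose and 9 fell (8 and 9 adjusted over the list alone, 0.638), and from prehypertrophic to hypertrophic 10 rose and 7 fell (10 and 7 adjusted over the list alone, 0.187). Of 22 Wnt genes, 8 rose and 10 fell from proliferative to hypertrophic (8 and 10 adjusted over the list alone, 0.827), 11 rose and 5 fell from proliferative to prehypertrophic (12 and 5 adjusted over the list alone, 0.337), and 8 rose and 9 fell from prehypertrophic to hypertrophic (8 and 9 adjusted over the list alone, 0.638). The Wnt antagonist Frzb rose by 4.49 ± 0.07 and the Wnt target Axin2 by 3.19 ± 0.13 between the outer zones, while the receptor Fzd1 fell by 4.17 ± 0.08. Of 24 FGF, IGF and growth hormone genes, 9 rose and 7 fell from proliferative to hypertrophic (9 and 8 adjusted over the list alone, 0.564), 5 rose and 5 fell from proliferative to prehypertrophic (5 and 4 adjusted over the list alone, 0.99), and 9 rose and 7 fell from prehypertrophic to hypertrophic (9 and 8 adjusted over the list alone, 0.638). The phosphatase Dusp6, induced by FGF signalling, rose by 4.24 ± 0.14 between the outer zones.

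Cell surface, protease, resting chondrocyte and secretory genes also went both ways. Camera called none of the pairs in this paragraph, and fry called all of them but the resting list from proliferative to prehypertrophic (adjusted p = 0.151). Of 32 cell surface genes, 15 rose and 11 fell from proliferative to hypertrophic (15 and 11 adjusted over the list alone, 0.633), 8 rose and 12 fell from proliferative to prehypertrophic (8 and 13 adjusted over the list alone, 0.395), and 14 rose and 11 fell from prehypertrophic to hypertrophic (15 and 12 adjusted over the list alone, 0.531). Cd34, a marker of vessel and blood stem cells, rose by 4.05 ± 0.16 over that last step, beside the endothelial and leukocyte markers. Of 20 proteases and inhibitors, 10 rose and 9 fell from proliferative to hypertrophic (10 and 9 adjusted over the list alone, 0.716), 4 rose and 8 fell from proliferative to prehypertrophic (4 and 8 adjusted over the list alone, 0.638), and 10 rose and 7 fell from prehypertrophic to hypertrophic (10 and 7 adjusted over the list alone, 0.275). The inhibitor Timp3 rose by 2.88 ± 0.06 between the outer zones, and the membrane protease Mmp14 fell by 2.02 ± 0.03 at the first step. Of 11 resting or superficial chondrocyte genes, 3 rose and 3 fell (3 and 3 adjusted over the list alone, 0.85), 3 rose and 2 fell (3 and 2 adjusted over the list alone, 0.99) and 5 rose and 4 fell (5 and 4 adjusted over the list alone, 0.797) in the same order, with Wif1 at 1.40 ± 0.10 between the outer zones. Secretory and unfolded protein response genes were not called from proliferative to hypertrophic (7 of 21 higher, 11 lower, 7 and 11 adjusted over the list alone, 0.395) or to prehypertrophic (9 higher, 9 lower, 10 and 9 adjusted over the list alone, 0.85), and the glutathione-degrading enzyme Chac1 rose by 3.07 ± 0.05 to the prehypertrophic zone.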
